A study of Arabidopsis thaliana with 6 samples.

How the data were processed

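Messenger RNA was measured by 3' RNA-seq in 6 libraries from whole shoots of 2-week-old Arabidopsis thaliana, 3 from the wild type Col-0 and 3 from the mutant los2-5. Per the labels' protocols, each replicate pooled 3 plants and the replicates came from different pots. Seeds on soil were kept at 4 °C for 2 days and the plants then grew at 22 °C under constant light of 100 µmol m-2 s-1 and 60% humidity. RNA was extracted with TRIzol, per the same protocols.

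The authors deposited 1 table of raw read counts per gene for 37051 genes, and these counts were used as deposited. The submitters' processing notes name STAR, edgeR and the genome build TAIR10, with no versions. The counting tool, the gene annotation and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical family members, may therefore not be separated in these counts. All 37051 gene identifiers matched locus tags of the TAIR10.1 RefSeq annotation, which was used for names, product descriptions, exonic GC content, and gene order and spacing. No coordinates are given, because that assembly carries another name than the authors' build. Symbols follow the reference, so that ICS1 appears as EDS16, PR2 as BGL2, CBF3 as DREB1A, ZAT10 as STZ, SOC1 as AGL20, RD29A as LTI78 and HSP90.7 as SHD. The table listed 0 plastid or mitochondrial genes, and every one of its columns matched 1 sample.

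Library totals ran from 3563033 to 4598645 counts. Genes were kept with filterByExpr at its defaults (a minimum count of 10 and a total of 15), which left 13952 genes holding 99.5% of the counts, while 14966 genes had 0 counts in all 6 libraries. Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust = TRUE, glmQLFTest) in R 4.3.3, with genotype as the sole term. The P values were adjusted by Benjamini-Hochberg over all genes kept and a gene was called at an adjusted p of at most 0.05. The common dispersion was 0.0155, a biological coefficient of variation of 0.125. Standard errors of log2 fold changes were derived as the absolute log2 fold change divided by the square root of F. All fold changes are los2-5 over Col-0, and levels are CPM on TMM-scaled library sizes, given as mean ± SD with n = 3 per genotype. Where a genotype had 0 counts of a gene, the fold was computed against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with an exact 95% interval. Such intervals and floors cover counting error alone.

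Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and adjustment over the 22 lists that had at least 5 genes tested. The same lists were tested by camera with an estimated correlation. That setting also takes its degrees of freedom from the residuals of the 6 libraries rather than from the number of genes, which by itself raises p. They were also tested with fry, which asks whether the members of a list move and does not compare them with other genes. With 2861 of the 13952 genes called, its test for change in either direction can give a small p for a list no different from other genes. Its directional test asks for a shift of the list in a single direction. The 19 lists of named genes held 348 entries and covered enolases, characterised NLR genes, short TIR and RPW8-like genes, salicylic acid immunity, pattern-triggered immunity, jasmonate and ethylene defence, camalexin and indole glucosinolates, aliphatic glucosinolates, cytosolic glycolysis, cold response, photosynthesis, cell cycle, ER folding, heat shock, senescence, the circadian clock, and root, flower and seed markers. Further lists were taken from reference descriptions or symbols: NLR genes with their TIR, CC and RPP5/SNC1 parts, receptor-like proteins, WRKY factors, cysteine-rich receptor-like kinases and ribosomal proteins. The lists, the tests and the alternatives not named below as added were fixed before the data were examined.

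The genes named in the text were chosen by a rule fixed at the same time. It took the 12 largest rises and the 12 largest falls among called genes with a mean of at least 2 CPM and no overlap between the genotypes. It added the enolases, up to 4 called members of each list with the smallest p and 10 for the NLR lists, and SNC1, RPP4, PR1, BGL2, PR5, EDS16, PAD4, EDS1 and STZ. Other genes named in the text were picked after their values were seen.

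The procedure was tested on simulated counts drawn for the 13952 genes at the real depths. Changes of 1.5-, 2- and 4-fold were put into 67, 67 and 66 genes, and a further list was raised 1.5-fold. At a 4-fold change 97.0% of changed genes were recovered, at a 2-fold change 82.1% and at a 1.5-fold change 23.9%. Of 159 calls 10 were false (6.29%), and 1 of 200 lists without any simulated change had p below 0.05 with camera. Each gene was simulated independently of the others, so this share of lists does not cover real lists whose genes vary together. The real comparison called 2861 genes, so the adjustment over genes was stricter in the simulation. Its recovered shares need not hold for the real data.

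Alternatives tried were DESeq2 1.42.0 size factors, library size alone, no filter, a filter of 2 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, a fit without the robust option, a replicate block, each library left out in turn, and an adjusted p of at most 0.01. A filter of 5 CPM, library size alone for the lists, and removal of a loess trend on GC content for the lists were added after the data had been seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.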

Results

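The transcriptomes of whole shoots were compared between Col-0 and los2-5, with 3 biological replicates of each genotype. LOS2 encodes a cytosolic enolase, an enzyme of glycolysis, and los2-5 is named as an allele of it. The series title places the question in plant immunity: whether the loss of enolase function raises the expression of genes for NLR proteins, the intracellular immune receptors of plants. Col-0 replicates 1 to 3 held 3563033, 4291282 and 4598645 counts, and los2-5 replicates 1 to 3 held 4454870, 4400433 and 4537653. Between 18997 and 19762 genes were detected per library, and the 10 most abundant genes took 15.1% to 16.4% of the counts. Each replicate, a pool of plants from its own pots, was counted as 1 sample. The first principal component, with 58.5% of the variance, placed the Col-0 libraries at -34.5, -29.5 and -35.8 and the los2-5 libraries at 20.8, 38.8 and 40.3.

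LOS2 (AT2G36530) itself was measured at 110, 124 and 106 CPM in the Col-0 libraries and at 120, 115 and 123 CPM in the los2-5 libraries. Its log2 fold change was 0.08 ± 0.12 (SE), with an adjusted p of 0.71 from the edgeR quasi-likelihood test. A 3' tag outside the lesion checks nothing about the genotype, and the position of the lesion is not given in the sources used here. Of the 3 enolase genes 0 were called by edgeR, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. DESeq2 and limma-voom also called 0. ENOC, which overlaps the more abundant PCNA2 on the opposite strand, had a log2 fold change of -0.22 ± 0.22. The value for ENO1 was -0.08 ± 0.31, and it turned to 0.039 when libraries were scaled by library size alone and to 0.12 without Col-0 replicate 3.

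In los2-5, 26 of 28 tested genes of salicylic acid immunity, 39 of 71 annotated NLR genes and 17 of 24 receptor-like protein genes rose, and 11 of 13 cold-response genes and 23 of 32 photosynthesis genes fell. Camera called all 5 lists with a preset correlation, and of these calls that of photosynthesis held with an estimated correlation (adjusted p = 0.025), where the others had an adjusted p of 0.078, 0.078, 0.097 and 0.10. PR1, the classic marker of salicylic acid signalling, went from 15.9 ± 10.1 CPM (SD, n = 3) in Col-0 to 401 ± 165 CPM in los2-5, a log2 fold change of 4.68 ± 0.67. The NLR gene ZAR1 rose from 99.7 ± 4.81 to 224 ± 50.4 CPM (log2 fold change 1.17 ± 0.15). COR15A, which encodes a chloroplast protein made in the cold, fell from 396 ± 81.5 to 45.8 ± 12.9 CPM (-3.11 ± 0.20). The photosystem I subunit gene PSAF fell from 8160 ± 685 to 3924 ± 425 CPM (-1.06 ± 0.12).

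Of the 13952 genes tested, 2861 were called by the edgeR quasi-likelihood test at an adjusted p of at most 0.05, with 1384 higher and 1477 lower in los2-5. Among these, 547 were higher and 315 lower by an absolute log2 fold change of at least 1. The libraries of the genotypes did not overlap for 5194 genes (37.2%), against 10% by chance. The split depended on scaling: higher genes made up 48.4% of the calls with TMM and 68.8% with library size alone (2179 higher, 989 lower), a scaling under which the fold changes shifted by a median of 0.12. Without Col-0 replicate 3 the total was 1758 (831 higher, 927 lower), the DESeq2 Wald test called 873 genes higher, and without los2-5 replicate 1 the genes lower by a log2 fold change of 1 or more numbered 525.

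**Figure D1:**
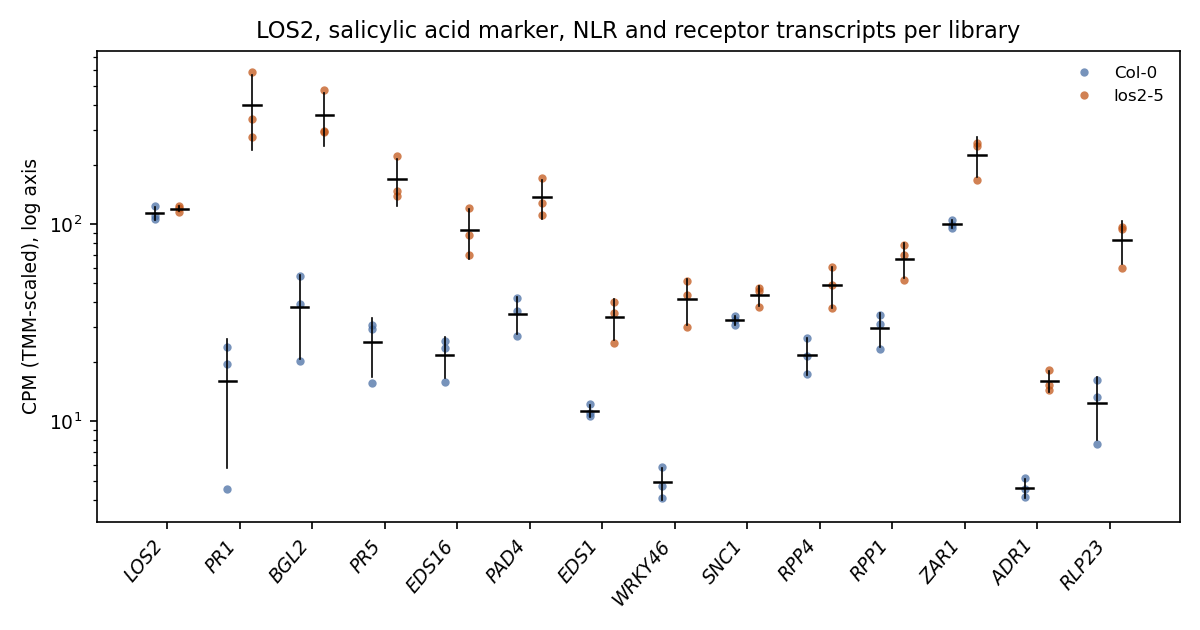
LOS2, salicylic acid marker, NLR and receptor transcripts in CPM on TMM-scaled library sizes (vertical log axis), with 1 point per library, 3 Col-0 libraries on the left and 3 los2-5 libraries on the right of each gene, horizontal bars for means and vertical bars for 1 SD. LOS2 means were 113 and 119 CPM, while for PR1 they were 15.9 and 401 CPM.

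Salicylic acid immunity showed the broadest rise: of 34 genes in the list 28 were tested, 26 rose, 0 fell and 2 were not called, with 27 rising adjusted over the list alone. At an unadjusted p under 0.05, 0 were lower in edgeR, and DESeq2 called 25 higher and 0 lower. The median log2 fold change was 1.93. The biosynthetic gene EDS16 (isochorismate synthase) rose from 21.6 ± 5.08 to 92.9 ± 26.2 CPM, a log2 fold change of 2.12 ± 0.21. PAD4 and EDS1, which encode lipase-like partners needed for signalling by many NLR proteins, rose by 1.97 ± 0.18 and 1.57 ± 0.20. The pathogenesis-related genes BGL2 and PR5 rose by 3.24 ± 0.41 and 2.75 ± 0.26 (adjusted p = 0.0043 and 3.9e-05, edgeR). DMR6, which encodes a salicylic acid hydroxylase, rose by 2.56 ± 0.18 (adjusted p = 2.8e-09, edgeR). The members not called were ACD6 (0.79 ± 0.25) and NDR1 (0.31 ± 0.22). Without Col-0 replicate 1 the adjusted p of ACD6 was 6.9e-05, in a range of 2.2e-07 to 0.16. Camera placed the list above other genes with an adjusted p of 5.6e-26, and the adjusted p was 0.078 with an estimated correlation. The adjusted p of PR1 was 0.013 in edgeR and 0.061 without Col-0 replicate 1, within a range of 8.2e-09 to 0.094 over all alternatives.

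NLR genes moved in 1 direction among those called. Of 154 genes annotated as NLR in the reference, 71 were tested: 39 rose, 0 fell and 32 were not called, with 47 rising and 0 falling adjusted over the list alone. At an unadjusted p under 0.05 edgeR had 50 higher and 0 lower, DESeq2 called 25 higher and 0 lower, and limma-voom 37 and 0. In this list 67 of the 71 had a log2 fold change above 0, and the median was 0.79. Those in the TIR class counted 24 risen of 46 tested (30 adjusted over the list alone; median 0.79), and those in the CC class 10 of 15 (12 adjusted over the list alone; median 0.74), with 0 falling in either (also 0 at an unadjusted p under 0.05, with DESeq2 and with limma-voom). DESeq2 called 17 of the TIR class and 3 of the CC class higher. AT5G41750, a TIR-class gene, rose from 3.62 ± 0.28 to 18.9 ± 2.01 CPM (log2 fold change 2.38 ± 0.23). ADR1, a helper NLR of the CC type, rose by 1.78 ± 0.23. AT3G44630 rose by 1.33 ± 0.17, RPP1 by 1.16 ± 0.17, AT5G36930 by 1.14 ± 0.20 and AT1G61190 by 0.81 ± 0.14. AT1G58602 rose by 1.14 ± 0.14, with 126 ± 8.48 CPM in Col-0 and 278 ± 57.7 CPM in los2-5.

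Camera gave the annotated NLR list an adjusted p of 1.5e-15, and the adjusted p was 0.078 with an estimated correlation. For the TIR class these were 1.2e-11 and, as the adjusted p with an estimated correlation, 0.096. For the CC class they were 4.6e-06 and, as the adjusted p with an estimated correlation, 0.053. The list of 45 characterised NLR genes, of which 30 of the tested members are also in the annotated list, had 37 tested, 19 risen, 0 fallen and 18 not called (24 risen adjusted over the list alone; median 0.79). Its camera adjusted p was 2.1e-10, and the adjusted p was 0.069 with an estimated correlation. Taken as a union, the lists held 78 tested genes, of which 42 rose and 0 fell in edgeR, with 54 and 0 at an unadjusted p under 0.05, 27 and 0 in DESeq2 and 40 and 0 in limma-voom.

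In the RPP5/SNC1 cluster, a tandem array of TIR-class NLR genes on chromosome 4, 5 of 9 genes were tested, 3 rose, 0 fell and 2 were not called. All 5 rose adjusted over the list alone, while DESeq2 and limma-voom each called 2. RPP4 rose by 1.16 ± 0.19 and RLM3 by 0.79 ± 0.13. SNC1 rose from 32.4 ± 1.73 to 43.5 ± 5.05 CPM, a log2 fold change of 0.42 ± 0.15 with an adjusted p of 0.047 in edgeR. The adjusted p of SNC1 ranged from 0.011 to 0.15 over 15 alternatives and was above 0.05 in 8 of them. Without Col-0 replicates 1, 2 and 3 in turn it was 0.15, 0.11 and 0.11, and without los2-5 replicates 2 and 3 it was 0.12 and 0.14. RPP5 (0.41 ± 0.17) and AT4G16900 (0.58 ± 0.22) were not called over all genes. The adjusted p of camera for the cluster was 6.4e-04, and the adjusted p was 0.10 with an estimated correlation. Members of such arrays are similar in sequence, so single values within them are uncertain where reads could be shared.

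Short TIR and RPW8-like genes counted 6 risen, 0 fallen and 2 not called among 8 tested of 10, with the same 6 and 0 adjusted over the list alone and a median of 1.15. AT1G57630 rose by 2.65 ± 0.36, HR4 by 1.87 ± 0.26, AT1G66090 by 1.53 ± 0.27 and HR3 by 1.63 ± 0.41. The description of AT1G66090 (TIR-NBS class) also places it in the annotated NLR list, so the lists are not separate. HR3 had an adjusted p of 0.053 in edgeR without Col-0 replicate 3, in a range of 7.6e-04 to 0.053. Camera gave the list an adjusted p of 9.5e-06, and the adjusted p was 0.10 with an estimated correlation.

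Genes for many receptors at the cell surface rose as well. Among receptor-like proteins, which lack a kinase domain, 24 of 54 were tested: 17 rose, 1 fell (RLP51, -1.87 ± 0.36) and 6 were not called, with the same counts adjusted over the list alone and a median of 1.32. DESeq2 called 11 higher and 1 lower. Without los2-5 replicate 1 the value of RLP51 was -2.53. RLP23, a receptor for a conserved peptide of microbial NLP proteins, rose from 12.4 ± 4.34 to 83.2 ± 20.5 CPM (log2 fold change 2.77 ± 0.25). RLP49 rose by 2.09 ± 0.20 and RLP34 by 1.56 ± 0.21. RLP28 had 1 count in the Col-0 libraries together and 40 in the los2-5 libraries, a ratio of 34.2 (exact 95% interval 5.80 to 1384), with the 1 count in Col-0 replicate 2. Camera gave an adjusted p of 5.8e-09, and the adjusted p was 0.097 with an estimated correlation. The pattern-triggered immunity list, which shares RLP23 with this one, had 10 risen, 0 fallen and 7 not called of 17 tested out of 32, with 10 rising adjusted over the list alone and a median of 0.66. DESeq2 called 6 of them higher and 0 lower. Its members SOBIR1 and BIR1, kinases that work with such receptors, rose by 1.39 ± 0.16 and 1.46 ± 0.16, and AT4G08850 rose by 0.90 ± 0.19. FLS2, the flagellin receptor gene, was at 0.66 ± 0.38 and not called. The camera adjusted p was 8.6e-07, and the adjusted p was 0.13 with an estimated correlation.

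Cysteine-rich receptor-like kinases had 14 genes risen, 1 fallen (CRK21, -0.87 ± 0.19) and 6 not called among 21 tested of 40, with the same counts adjusted over the list alone. The median was 1.49, and it stayed there with CRK37 set to its bound. The list holds 2 CDPK-related kinases that share the CRK symbol, and without them 13 of 19 rose. CRK4 rose by 2.90 ± 0.26 and CRK6 by 2.30 ± 0.22. CRK37 had 0 counts in Col-0 and was at least 15.4-fold higher in los2-5, and CRK7 had 1 count against 73, a ratio of 62.4 (exact 95% interval 10.9 to 2499), with the 1 count in Col-0 replicate 1. The camera adjusted p was 7.6e-10, and the call held with an estimated correlation (adjusted p = 0.025). Among WRKY transcription factors, 25 of 67 were tested, 14 rose, 1 fell (WRKY11, -1.05 ± 0.27) and 10 were not called, with 14 rising and 2 falling adjusted over the list alone and a median of 0.85. WRKY46 rose from 4.90 ± 0.93 to 41.7 ± 10.7 CPM (log2 fold change 3.08 ± 0.23), WRKY38 by 2.97 ± 0.41, WRKY18 by 2.21 ± 0.31 and WRKY25 by 1.26 ± 0.19. Without Col-0 replicate 1 the log2 fold change of WRKY38 was 4.14. Of the tested WRKY genes 7 are also in the salicylic acid or pattern lists. The camera adjusted p was 4.9e-06, and the adjusted p was 0.069 with an estimated correlation.

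**Figure D2:**
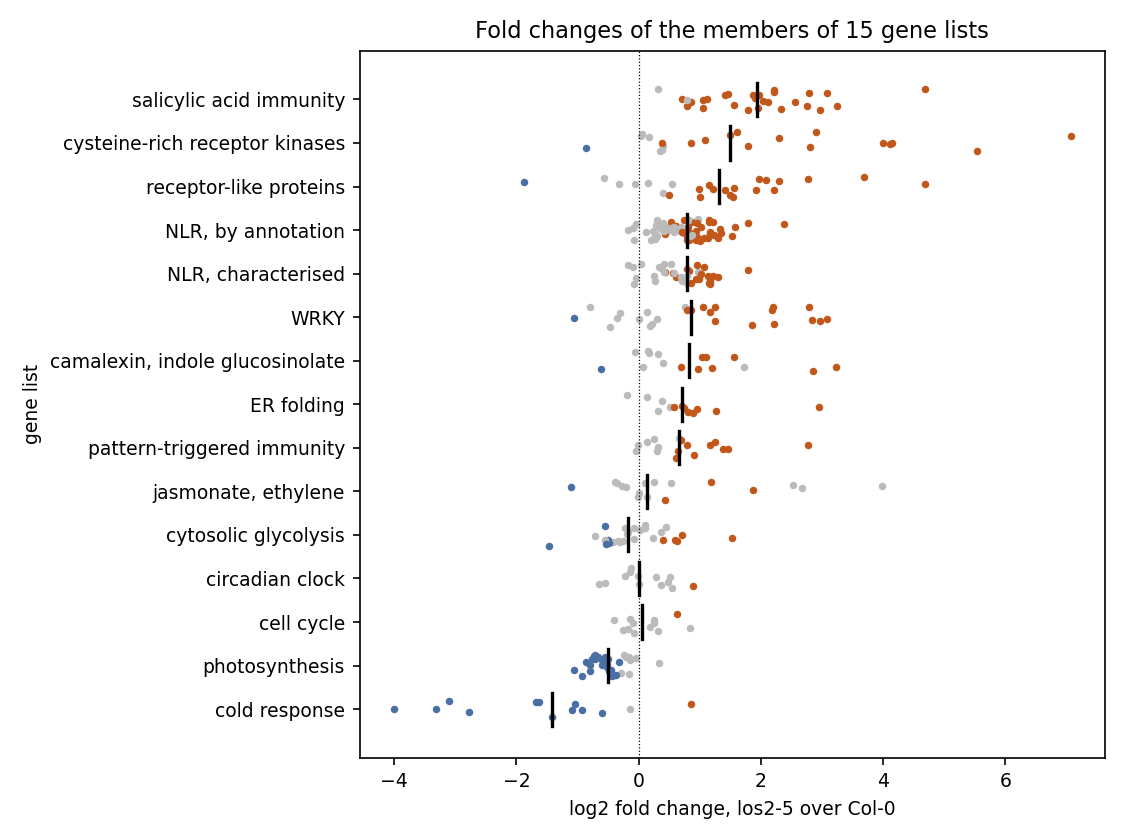
Log2 fold change of los2-5 over Col-0 (horizontal axis) for each tested gene of 15 gene lists (vertical axis), with orange points for genes called higher, blue for genes called lower, grey for genes not called, and a black bar at each list's median. The medians ran from 1.93 for salicylic acid immunity to -1.42 for cold response, and the point at 7.07 is the fitted value of CRK37, which had 0 counts in Col-0.

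The cold response list moved the other way. Of 19 genes 13 were tested: 11 fell, 1 rose and 1 (ICE1, -0.14 ± 0.25) was not called, with the same 11 and 1 adjusted over the list alone, and the median was -1.42. Besides COR15A, the genes KIN1 (-3.32 ± 0.40), GolS3 (-2.78 ± 0.45), COR15B (-1.64 ± 0.20) and COR413-PM1 (-1.09 ± 0.13) fell. DREB1A, which encodes a transcription factor that activates these genes in the cold, had 47 counts in the Col-0 libraries together and 3 in the los2-5 libraries, 18.3-fold lower (exact 95% interval 5.90 to 92.0). All 3 of these counts were in los2-5 replicate 1, and without it the fitted log2 fold change of DREB1A went from -4.01 to -7.06. The member that rose was STZ, a zinc finger repressor gene described as a target of LOS2, from 5.90 ± 0.64 to 10.7 ± 1.82 CPM (log2 fold change 0.86 ± 0.24, adjusted p = 0.012, edgeR). Its adjusted p was 0.061 without Col-0 replicate 2, in a range of 0.0054 to 0.073 over the alternatives, and DESeq2 called 0 of the list higher and 11 lower. Camera gave the list an adjusted p of 1.7e-10, and the adjusted p was 0.10 with an estimated correlation. KIN1 and its neighbour KIN2, and COR15A and COR15B, are near copies, so their separate values are uncertain.

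All 32 photosynthesis genes were tested, and 23 fell, 0 rose and 9 were not called. Adjusted over the list alone, 24 fell and 1 (HEMA1, 0.34 ± 0.14) was higher. DESeq2 and limma-voom each called 23 lower and 0 higher. HEMA1 had an adjusted p over all genes of 0.040 without Col-0 replicate 2 and 0.042 without los2-5 replicate 1, in a range of 0.022 to 0.39. The median log2 fold change was -0.50, and with library size alone it was -0.37. Relative to all genes it was then -0.52, a value that a change of scaling leaves nearly fixed. RBCS1A, a gene of the small subunit of Rubisco, fell from 13404 ± 696 to 7912 ± 972 CPM (-0.76 ± 0.12), and RBCS3B fell as well (-0.79 ± 0.11). GAPA, a gene of the Calvin cycle, had a log2 fold change of -0.86 ± 0.13. Camera gave an adjusted p of 1.2e-12, and the call held with an estimated correlation (adjusted p = 0.025). The RBCS and chlorophyll-binding genes have near-identical copies, so the split between copies is uncertain.

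**Figure D3:**
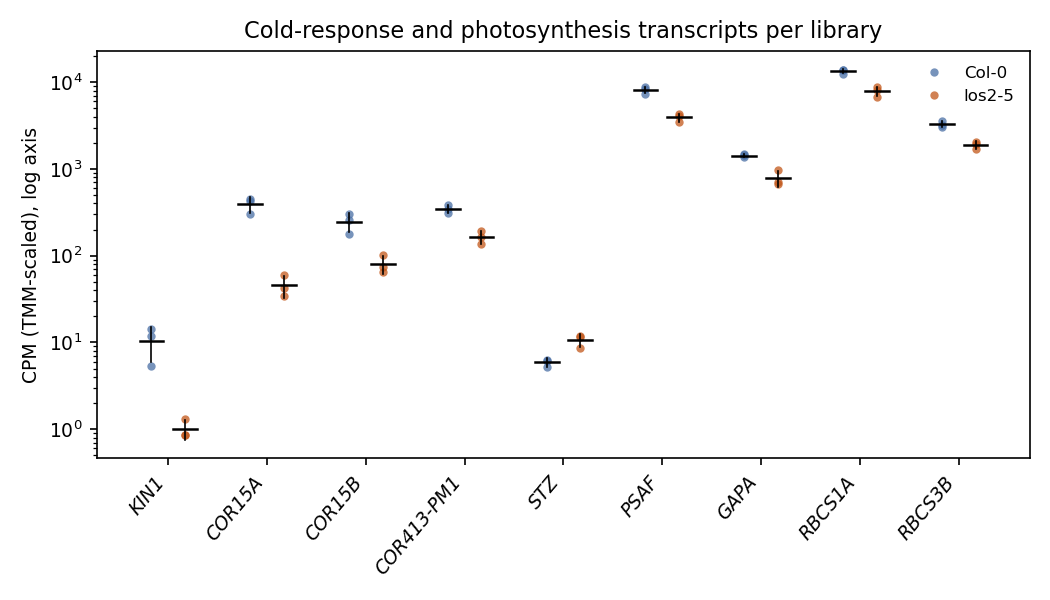
Cold-response and photosynthesis transcripts in CPM on TMM-scaled library sizes (vertical log axis), with 1 point per library, 3 Col-0 libraries on the left and 3 los2-5 libraries on the right of each gene, horizontal bars for means and vertical bars for 1 SD. COR15A means were 396 and 45.8 CPM, and STZ had means of 5.90 and 10.7 CPM.

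Genes of camalexin and indole glucosinolate synthesis had 8 risen, 1 fallen (TSB1, -0.61 ± 0.17) and 7 not called among 16 tested of 18, with 10 and 1 adjusted over the list alone and a median of 0.83. Without Col-0 replicate 3 and los2-5 replicate 3 in turn, the adjusted p of TSB1 was 0.13 and 0.060, in a range of 0.0051 to 0.13. CYP71A12 rose by 2.85 ± 0.49, GSTF6 by 1.56 ± 0.17 and SOT16 by 0.69 ± 0.13, and CYP79B2 rose to 39.7 ± 3.85 CPM with an adjusted p of 4.4e-04 in edgeR. Camera gave an adjusted p of 1.0e-05, and the adjusted p was 0.13 with an estimated correlation. Aliphatic glucosinolate genes had 2 risen, 0 fallen and 9 not called among 11 tested of 12, unchanged in number when adjusted over the list alone, while DESeq2 and limma-voom each called 1 higher. SOT17 was at 0.84 ± 0.18 and IMS2 at 1.19 ± 0.39, the latter with an adjusted p of 0.019 to 0.20 over the alternatives. For IMS2 it was 0.086, 0.11 and 0.095 without Col-0 replicates 1, 2 and 3, and 0.13 and 0.070 without los2-5 replicates 2 and 3. The camera adjusted p was 0.080, in a range up to 0.61. It was 0.033 without Col-0 replicate 1, 0.035 without Col-0 replicate 3 and 0.0079 without los2-5 replicate 1. For change in either direction fry gave an adjusted p of 0.029, and its directional test gave 0.26.

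ER folding genes, which help secreted proteins and receptors to fold, had 8 risen, 0 fallen and 5 not called among 13 tested of 14, with 11 and 0 adjusted over the list alone and a median of 0.71. BIP3 rose from 4.70 ± 1.63 to 35.9 ± 10.4 CPM (log2 fold change 2.94 ± 0.27). CRT3, a calreticulin gene, rose by 1.27 ± 0.13, SHD by 0.96 ± 0.14 and ATERDJ3B by 0.80 ± 0.14. Camera gave an adjusted p of 1.4e-07, and the adjusted p was 0.10 with an estimated correlation.

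Jasmonate and ethylene defence genes were not called as a group by camera. Of 25 genes 17 were tested: 3 rose, 1 fell and 13 were not called by edgeR, with the same 3 and 1 adjusted over the list alone. DESeq2 and limma-voom each called 4 higher and 1 lower. The list holds the defensin genes PDF1.2, PDF1.2c and PDF1.3, which were not called and had low counts in los2-5 replicate 2. Without that library edgeR called them (adjusted p = 8.1e-05, 4.1e-04 and 1.1e-08). AOS, a gene of jasmonate synthesis, fell from 342 ± 18.9 to 158 ± 10.6 CPM (-1.11 ± 0.12). ORA59 rose by 1.18 ± 0.27 and VSP1 by 1.88 ± 0.45. PR4 was at 0.43 ± 0.14, and its log2 fold change was 0.27 (adjusted p = 0.18, edgeR) without los2-5 replicate 1, in a range of 0.0074 to 0.18. Without Col-0 replicates 1, 2 and 3 the adjusted p of PR4 was 0.10, 0.082 and 0.12. The adjusted p of VSP1 was 0.056 without los2-5 replicate 2, in a range of 4.5e-04 to 0.056. Camera gave the list an adjusted p of 0.24, which was 0.031 without los2-5 replicate 2, in a range up to 0.42. For change in either direction fry gave an adjusted p of 6.9e-05, and its directional test gave 0.12.

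Cytosolic glycolysis genes other than enolase split evenly. Of 29 genes 27 were tested: 5 rose, 5 fell and 17 were not called, with 6 and 6 adjusted over the list alone and a median of -0.17. PFK3, a phosphofructokinase gene, rose from 5.52 ± 1.04 to 15.9 ± 2.86 CPM (log2 fold change 1.53 ± 0.23). AT5G63680, a pyruvate kinase gene, rose by 0.70 ± 0.14 and GAPC1 by 0.59 ± 0.12, with ALDH11A3 and PPC2 as the other risen members. PPC2 had an adjusted p of 0.13, 0.063 and 0.18 without Col-0 replicates 1, 2 and 3 and of 0.16 and 0.13 without los2-5 replicates 2 and 3, in a range of 0.0054 to 0.18. TPI, the triose phosphate isomerase gene, fell (-0.54 ± 0.12), and FBA5, FBA8, PGM2 and PPDK fell as well. The adjusted p of FBA5 was 0.055 without los2-5 replicate 2, in a range of 0.0021 to 0.055, and that of PGM2 was 0.11 without Col-0 replicate 2 and without los2-5 replicate 2, in a range of 0.0052 to 0.11. Camera gave an adjusted p of 0.59, fry's test for change in either direction an adjusted p of 0.0012 and its directional test 0.28.

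In the cell cycle list 12 of 18 were tested and 1 was called, SYP111 at 0.63 ± 0.18 (also 1 adjusted over the list alone; 0 with DESeq2; camera adjusted p 0.59), which overlaps the more abundant NPQ1 on the opposite strand. The adjusted p of SYP111 ranged from 0.0061 to 0.10 and was 0.10 without Col-0 replicate 1 and 0.074 without los2-5 replicate 2. The circadian clock list had 13 of 14 tested and 1 called, LHY at 0.89 ± 0.19, with 2 higher and 2 lower adjusted over the list alone and a camera adjusted p of 0.40. DESeq2 and limma-voom each called 1 higher and 1 lower there. Fry's test for change in either direction gave an adjusted p of 0.070 for the cell cycle and 0.14 for the clock. In the senescence list 6 of 10 were tested, and SAG21 (1.82 ± 0.16) and NYE1 (0.67 ± 0.17) rose, with 3 higher and 2 lower adjusted over the list alone. Its camera adjusted p was 0.16, and 0.026 without Col-0 replicate 3, in a range up to 0.46. For change in either direction fry gave the senescence list an adjusted p of 3.0e-04, and its directional test gave 0.11. DESeq2 called 3 senescence genes higher and 0 lower, and limma-voom 3 and 1. Of the heat shock genes 4 of 11 were tested and 1 rose, HSP70 by 1.71 ± 0.27, also adjusted over the list alone. Too few were tested for camera, but where 6 passed the filter it gave upward calls without Col-0 replicate 1 (adjusted p = 0.022), Col-0 replicate 3 (0.021) and los2-5 replicate 1 (0.016), in a range up to 0.099. With 1 library left out the filter asks for 2 libraries rather than 3. HSP90.1 (7, 5 and 4 counts in Col-0, 6, 43 and 34 in los2-5) then passed through its high los2-5 replicates 2 and 3. These upward calls thus include a member kept because it was high in los2-5, and they decide nothing about the list.

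Among root markers 1 of 7 passed the filter, PYK10 at -0.08, which was not called. Of 11 flower and transition genes 2 were tested and both were called, also adjusted over the list alone: AGL20 at 0.67 ± 0.20 and FLC, a repressor of flowering, at 1.37 ± 0.42. The adjusted p of AGL20 ranged from 0.0069 to 0.093 and that of FLC from 0.0066 to 0.16. That of AGL20 was 0.066, 0.082 and 0.093 without Col-0 replicate 1, Col-0 replicate 2 and los2-5 replicate 2. That of FLC was 0.084, 0.16, 0.053 and 0.065 without Col-0 replicate 1, Col-0 replicate 3, los2-5 replicate 2 and los2-5 replicate 3, and its log2 fold change was 2.098 without Col-0 replicate 2. DESeq2 called 0 of the 2 and limma-voom both. None of the 4 seed storage markers passed the filter, with 1 count in total across the 6 libraries. Ribosomal protein genes had 15 risen, 35 fallen and 234 not called among 284 tested of 326 (13 and 33 adjusted over the list alone). At an unadjusted p under 0.05 edgeR had 40 higher and 49 lower, and DESeq2 called 6 higher and 35 lower. Their median was 0.02, their mean -0.03 and the direction of camera downward (adjusted p = 0.59), which turned upward with library size alone (adjusted p = 0.65), without Col-0 replicate 2 (0.92) and without los2-5 replicate 3 (0.42). Fry's test for change in either direction gave an adjusted p of 5.0e-04, and its directional test gave 0.73. The members with the smallest p were AT1G64510, EMB3113, EMB3137 and AT5G46160, which encode ribosomal proteins of the bacterial type found in organelles. They fell, with log2 fold changes of -0.91 ± 0.12, -0.87 ± 0.12, -0.74 ± 0.12 and -1.45 ± 0.24.

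The genes with the largest fitted rises at a mean of at least 2 CPM included AT4G10860 and GLP9, a germin-like protein gene. Both had 0 counts in Col-0 and were at least 25.4-fold and at least 20.5-fold higher in los2-5. AT1G21525 rose from 1.91 ± 1.67 to 82.9 ± 7.35 CPM (log2 fold change 5.52 ± 0.27, adjusted p = 6.3e-11, edgeR). AT5G63225 had 3 counts in Col-0 against 159, a ratio of 45.3 (exact 95% interval 15.2 to 222). The zinc finger gene AT3G46080 rose by 4.94 ± 0.49, the lipid-transfer family gene AT4G12490 by 4.62 ± 0.57, MSRB8 by 4.15 ± 0.63, scpl16 by 4.12 ± 0.53 and AT5G51465 by 4.08 ± 0.52. The oxygenase gene AT3G13610 rose by 4.39 ± 0.73, with an adjusted p of 0.058 without Col-0 replicate 1 in a range of 5.9e-08 to 0.058. Single libraries moved several of these log2 fold changes: without Col-0 replicate 1 they were 6.41 for AT1G21525, 6.29 for AT5G63225, 5.40 for AT5G51465 and 5.47 for MSRB8. Without Col-0 replicate 3 they were 4.72 for AT5G63225, 3.44 for AT5G51465, 3.51 for MSRB8 and 5.69 for AT4G12490. For AT3G13610 the value was 5.01 without Col-0 replicate 2 and 3.76 without los2-5 replicate 3. The genes scpl16 and AT5G51465 overlap another gene on the opposite strand with more counts, and AT5G65207 overlaps one on its own strand, so their values are uncertain. After DREB1A, KIN1 and COR15A, the next fitted falls were those of AT4G24090 (-2.89 ± 0.50), GolS3, AT1G04660 (-2.59 ± 0.31), the lipid-transfer gene LTP3 (-2.45 ± 0.27) and AT2G05995 (-2.41 ± 0.44). XTH31, a cell wall xyloglucan enzyme gene, fell from 42.3 ± 11.8 to 7.98 ± 3.25 CPM (-2.41 ± 0.26). AT1G30250 had a log2 fold change of -2.31 ± 0.24, the auxin-response gene IAA29 of -2.28 ± 0.37 and AT5G65207 of -2.13 ± 0.43.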

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

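The filter of 5 CPM, library size alone for the lists and the GC correction were chosen after the data had been seen. The total of 2861 genes called went to 1758 to 3143 when 1 library was left out, those higher to 831 to 1537 and those lower to 927 to 1606. The highest values came without los2-5 replicate 1, and the cause was not tested. An adjusted p of at most 0.01 left 1530 genes, 721 higher and 809 lower, with 791 (394 and 397) without Col-0 replicate 3, 527 lower without Col-0 replicate 1, 501 lower without los2-5 replicate 2, and 1092 higher and 461 lower with library size alone. The DESeq2 Wald test called 873 genes higher, and library size alone 2179. Genes lower by a log2 fold change of 1 or more numbered 205 with library size alone and 264 to 525 with 1 library left out. Of the 2861 genes, 1896 were shared with the DESeq2 Wald test, which gave no adjusted p for 7019 genes, 2373 with library size alone and 2680 with limma-voom. The planned filter of 2 CPM kept 14377 genes, more than the 13952 of the default, so it was not stricter. The planned removal of organelle genes was not run, because the table held 0 of them.

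Same-numbered libraries did not deviate together (correlations 0.051, -6.8e-04 and -0.048), and not every library correlated best with its own number. No label says that a number marks a shared batch, but 3 libraries per genotype are too few to exclude one. With the replicate number as a block, 3115 genes were called against 2861 without it, 1517 higher and 1598 lower. The adjusted p of PR1 was then 0.094 and that of BGL2 0.081, so neither was called.

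With an estimated correlation the adjusted p was 0.069 for the characterised NLR list, 0.078 for annotated NLR genes, 0.096 for the TIR class, 0.053 for the CC class, 0.10 for the RPP5/SNC1 cluster, 0.10 for short TIR and RPW8-like genes, 0.078 for salicylic acid immunity, 0.13 for pattern-triggered immunity, 0.13 for camalexin and indole glucosinolates, 0.10 for cold response, 0.10 for ER folding, 0.097 for receptor-like proteins and 0.069 for WRKY factors. The CC class lost its call at an estimated correlation of -5.2e-04, below the preset 0.01, so a higher correlation was not the cause there. The camera adjusted p of photosynthesis likewise went from 1.2e-12 to 0.025 at an estimated correlation of 0.012. That of cysteine-rich receptor-like kinases went from 7.6e-10 to 0.025 at -0.010. Larger p values with an estimated correlation thus reflect the fewer degrees of freedom of that setting as well as any correlation. In the other lists that lost their call the estimated correlation ran from 0.023 (WRKY factors) to 0.47 (cold response). It was 0.12 for annotated NLR genes and 0.38 for salicylic acid immunity. All of these lie above the preset 0.01, so correlation and degrees of freedom cannot be told apart there. Leaving out 1 library, the camera adjusted p ran from 0.031 to 0.42 for jasmonate and ethylene defence, 0.0079 to 0.41 for aliphatic glucosinolates, 0.026 to 0.32 for senescence and 0.19 to 0.92 for ribosomal proteins. The last list changed direction without Col-0 replicate 2, without los2-5 replicate 3 and with library size alone (0.65). ENO1 changed sign with library size alone (log2 fold change 0.039), a scaling that moved the median of all genes by 0.12, and had values from -0.28 to 0.12 with 1 library left out, where the cause was not tested. At this depth 23.9% of 1.5-fold changes were recovered in simulated counts. With 159 calls there against 2861 in the real data, the adjustment was stricter in the simulation, so this share need not hold here.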

Other observations

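The product families, the adjacency of genes that fell, the joint limit on gap and product, the interval set on each pair ratio and the interval on the odds ratio were chosen after the results had been seen. Genes were grouped by product description into 231 families with at least 8 tested members, and camera called 15 of them, 8 upward and 7 downward. With an estimated correlation camera called 0 of the 231 (lowest adjusted p 0.64, with 9 at an unadjusted p under 0.05). With the few residual degrees of freedom of that setting and adjustment over 231 families a call was hard to reach, so the 0 decides little about single families. The families below were called with the preset correlation alone. Arabinogalactan proteins of the cell wall had 10 of 19 genes fallen and 2 risen (median log2 fold change -0.64, camera adjusted p 8.9e-05). AGP21 fell from 1081 ± 132 to 393 ± 87.7 CPM (-1.46 ± 0.14). The 3-ketoacyl-CoA synthases, which elongate fatty acids for waxes and other lipids, had 5 of 14 fallen and 0 risen (median -0.45, adjusted p 0.0030), among them KCS20 (-1.11 ± 0.19) and KCS6 (-0.60 ± 0.14). Of the SAUR-like auxin-responsive genes 8 of 30 fell and 1 rose (median -0.43, adjusted p 0.019).

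Membrane proteins of the SPFH/band family had 6 of 10 genes risen and 0 fallen (median 0.85, adjusted p 0.0029), with FLOT1 at 39.5 ± 9.14 CPM in Col-0 and 193 ± 24.0 CPM in los2-5. Chitinases, enzymes that cut fungal cell wall chitin, had 5 of 8 risen and 1 fallen (median 1.07, adjusted p 0.020). CHI rose by 3.64 ± 0.42, and the member that fell was POM1 (-0.52 ± 0.13). Plant defensin genes were uneven within los2-5 and not called by edgeR. PDF1.2 had 5, 19 and 3 counts in the Col-0 libraries and 87, 13 and 83 in the los2-5 libraries, and PDF1.3 had 12, 27 and 21 against 234, 30 and 184. Limma-voom called PDF1.2 (adjusted p = 0.044) and PDF1.3 (0.027), DESeq2 called PDF1.2c (0.0094) and PDF1.3 (0.015), and without los2-5 replicate 2 edgeR called PDF1.2 (8.1e-05), PDF1.2c (4.1e-04) and PDF1.3 (1.1e-08). Over the alternatives the adjusted p reached 0.36, 0.33 and 0.32 for PDF1.2, PDF1.2c and PDF1.3. CBF2 had 8, 12 and 57 counts in Col-0 and 10, 3 and 10 in los2-5, and did not pass the filter. SAG13 had 2, 6 and 38 counts in Col-0 and 105, 89 and 239 in los2-5 (adjusted p = 0.088, edgeR), and its adjusted p was 0.0066 without Col-0 replicate 3, in a range of 2.2e-09 to 0.22.

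The rise of annotated NLR genes was set against 3 technical sources. The list median of 0.79 lay at percentile 100 of 10000 random lists matched on mean expression, whose highest median was 0.30, which argues against a general rise of weakly expressed genes. The 21 tested NLR genes with no other NLR gene within 50 kb had a median of 0.82 (bootstrap over genes 0.69 to 0.95) and 10 of them rose, which argues against reads shared within clusters as the whole source. After a loess trend on exonic GC content was removed the median was 0.69 (0.54 to 0.77), against 0.76 before. The bootstrap intervals here and for photosynthesis resampled genes, so they do not cover the spread between libraries. A candidate explanation that remains is a response to genotype, as a hypothesis that a second allele or a complemented line would test, neither of them analysed here, and its order relative to the salicylic acid response cannot be read from 1 time point.

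The fall of the photosynthesis list was weighed in the same way. The 1209 abundant genes outside the plastid had a median of -0.064 (bootstrap over genes -0.081 to -0.042), far from the -0.50 of the list, which argues against a scaling of abundant transcripts. With the GC trend removed the list median was -0.43 (-0.65 to -0.30) and camera still called it (adjusted p = 2.9e-10). Genotype remains as a hypothesis, not tested here with another allele or a complemented line, and a different mix of leaf ages or cell types in the shoots was not tested and stays open.

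With the tested genes alone placed in chromosome order, genes that rose were next to each other in 202 pairs, against 137 expected by permutation (p = 0.0001, the smallest that 10000 permutations can give). Genes that were not tested may lie between the members of a pair. Pairs more than 2 kb apart showed a ratio of observed to expected of 1.66 (1.36 to 1.99), which argues against reads that run on into the next gene. Without pairs that share a product the ratio was 1.24 (1.05 to 1.44, permutation p = 0.0015). The interval includes the bound of 1.2 set in advance. That limit dropped only pairs whose descriptions match apart from digits, so related neighbours such as CRK7 and CRK8 or WAK1 and WAK2 stayed in. Tandem copies such as CRK5, CRK6 and CRK7, if they share reads, may account for part of the excess. They cannot be told apart from clustered regulation. With both limits together the ratio was 1.46 (1.19 to 1.78), with WAK1 and WAK2 still among the pairs. Genes that fell gave 188 pairs against 156 expected (ratio 1.21, permutation p = 0.0031).

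Within 1 Mb of LOS2, 58 of 301 tested genes were called (19.3%), against 20.5% elsewhere (odds ratio 0.92, 95% interval 0.68 to 1.24, two-sided Fisher exact p = 0.66), so no excess of calls was detected there and a small one is not excluded. The 10 ways of splitting the 6 libraries into groups of 3 are too few for a share under 0.05. The genotype split, the 1 split with as many calls, gave 2861 genes in edgeR, and the highest of the other 9 gave 0, with 112 to 596 genes at an unadjusted p under 0.05 in those splits. Each of the other 9 mixes both genotypes in both groups, which widens the spread within groups. Few calls were therefore likely in them, and the contrast decides nothing.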
